A study of Homo sapiens with 384 samples.

How the data were processed

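Primary human skeletal muscle myoblasts were expanded in growth medium with 10% fetal bovine serum and differentiated by a switch to medium with 2% horse serum, per the labels' protocols. Cells were collected at 0, 24, 48 and 72 h after the switch. Bulk libraries (12, 3 per time) were made with a TruSeq mRNA kit from 100 ng of total RNA each, and the labels state that the 3 cultures of a time were independent biological replicates. For single cells the cultures of a time were pooled, captured on a C1 microfluidic plate, imaged, and converted to cDNA with SMARTer chemistry. The 372 single-cell libraries comprise 306 wells scored as holding 1 cell, 42 scored as empty, 7 with 2 cells, 11 with debris and 6 tube controls made from the RNA of about 250 cells. Each time was its own capture plate, so time and plate cannot be told apart in the single-cell data, and each time counts as 1 sample there.

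The values are FPKM per gene (fragment counts scaled by gene length and by library size) as deposited by the authors, in a bulk table and a single-cell table with the same 47192 gene identifiers. The submitters' processing notes name TopHat2 2.0.9, Bowtie2 2.0.6, TopHat, Cuffdiff 2.2 and the hg19 genome, without saying which step each served. How fragments were assigned to overlapping or antisense genes is not given in the sources used here. Neither library type is stated to keep strand, so values of genes named as antisense RNAs cannot be separated from those of their partners. The tables were normalized separately, so bulk and single cells were compared by correlation across genes and by direction, not by level. All sample columns were matched to the labels by name. The bulk columns carry suffixes 0 to 2 and the labels number replicates from 1 to 3, so bulk columns were assigned to a time but not to a replicate number.

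Gene symbols were looked up by Ensembl identifier and were found for 44113 genes. Y-linked genes and XIST (444 identifiers in all) were left out, leaving 46748. Coordinates are not printed, because the reference annotation at hand is of another build. Gene lists (27, with 606 different genes of which 604 were matched, through older symbols where needed) were fixed before the data were examined, as were the rule for named genes, the tests and most alternatives. FPKM totals are not depth. Relative depth was read from low values: a single fragment of a given gene is worth a fixed FPKM in a given library. Of 33331 low values compared in bulk, 74.3% were whole multiples of such a step within 3%, against 3.06% after multiplying by 1.26. In single cells it was 75.1% of 411105. The step of each gene was fitted on these same values, so values near 1 step match by construction and the contrast is no independent check. The bulk libraries of 0, 24 and 48 h had relative depths from 0.917 to 1.05, and those of 72 h from 1.64 to 2.01. The share of low values on which the estimate rested was 44.2 to 49.5% in the former and 21.3 to 26.3% in the latter. Single-cell wells with 1 cell had a median relative depth of 1.48 at 0 h, 0.984 at 24 h, 0.738 at 48 h and 0.970 at 72 h. The estimate gave a value in 75 of 81 wells at 0 h, 60 of 64 at 72 h and every well at 24 and 48 h, and only medians are given.

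Bulk genes at FPKM 1 or more in at least 3 of the 12 libraries were tested (14006). Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with all 12 libraries in 1 model with a term per time, moderated variances with a trend, and Benjamini-Hochberg adjustment within each comparison at 0.05. An F test asked which genes changed at any time. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists within each comparison. List p-values are those of camera at the preset correlation unless stated. Results of fry are not given here. On simulated values for the 24 h against 0 h comparison, with 13059 genes in the step, limma recovered 70.1% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2. It made 194 calls for 200 changed genes, 16 of them false, a share above the nominal 0.05. The changed genes were drawn only from those above FPKM 5 at 0 h, so recovery among lower genes was not measured. They were also far fewer than in the data, where 54.6% of tested genes were called in this comparison.

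Named bulk genes are the 10 highest and 10 lowest log2 fold changes for 72 h against 0 h and the 6 highest and 6 lowest for the day-by-day comparisons, among called genes with a mean FPKM of at least 10 in the higher time whose libraries did not overlap. A further 12 fixed genes are named in every comparison, along with up to 4 members of some lists. The rule fixed beforehand asked for the 2 to 4 called members of largest change of each list. The text follows it only in part, since members were first picked by eye, after the values were seen, and then brought closer to the rule. Unnamed identifiers and pseudogenes were skipped. In single cells the genes named are the 12 fixed genes, *MYH3*, *DES*, 8 transcription factors that the study singled out on these cells, and the 6 largest rises and 6 largest falls in the share of cells from 0 h to 72 h. Identifiers that stood in place of a symbol were treated as having none, a choice made after the values were seen, which admitted *MYL11* to the rises.

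A gene was called present in a cell at FPKM 1 or more. Wells scored as holding 1 cell entered with at least 1000 genes present, which left 75, 76, 85 and 59 cells at 0, 24, 48 and 72 h and removed 6 wells at 0 h and 5 at 72 h. Doublets were removed only through the image scores. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and no p-value was computed from cells. A sarcomere score was the mean log2(FPKM + 1) of 33 sarcomere list genes present in at least 5% of cells, and Spearman correlations with it were taken across cells within each time. Clusters (6) came from Ward clustering of 10 principal components of the 1000 most variable genes and were named from fixed markers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

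Alternatives changed the pseudocount, the filter on low values, the scaling between libraries, the variance trend and the libraries in the fit, and left out each bulk library in turn. For cells they changed the detection threshold, the minimum of genes and the wells admitted. A fit without the 72 h libraries, a fit with the column suffix as a block and a rescaling of cells to a common total were added after the data were examined. Correlations and rank relations were counted as moved when they differed by 0.05 or more, a tolerance set after the data were examined. *MYOG*, *CDK1* and *PDGFRA* were chosen as the shares whose alternatives are given in full, also after the data were examined.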

Results

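The data follow human skeletal muscle myoblasts, the proliferating precursors of muscle fibres, through 72 h of serum-withdrawal differentiation. Gene expression was measured as FPKM in 12 bulk libraries, 3 independent cultures at each of 0, 24, 48 and 72 h, and in single cells captured at the same times. The study asked whether ordering cells by their progress shows which genes regulate it. Bulk libraries of 1 time correlated at Pearson r of 0.987 to 0.993 across genes, and libraries of different times at 0.910 to 0.979, genes not being independent replicates. No pair of libraries held identical values. Between 12738 and 13309 genes were at FPKM 1 or more per bulk library. Mitochondrial transcripts held 7.91 to 8.49% of each library's FPKM. The 72 h bulk libraries had an estimated relative depth of 1.64 to 2.01, against 0.917 to 1.05 at the other times.

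Over the 4 times, 9845 of 14006 tested genes (70.3%) changed in the limma F test. The first 24 h held most of the change in number: 7646 genes changed from 0 to 24 h (3659 higher, 3987 lower), 3196 from 24 to 48 h (1676 higher, 1520 lower) and 4362 from 48 to 72 h (2321 higher, 2041 lower). By at least 2-fold, the counts were 1439, 238 and 215. These depend on the pseudocount: with 5 they were 654, 90 and 62, and with 0.1 the second day had 407 and the third 398. The median log2 fold change of all tested genes was -0.0040 on the first day, 9.2e-05 on the second and -0.0039 on the third. Some genes share sequence with close relatives, such as the metallothionein and myosin heavy chain genes, so the split of fragments among them is uncertain.

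In the first 24 h the muscle program came on. *MYOG*, the transcription factor of terminal muscle differentiation, went from 5.0 ± 0.93 to 239 ± 22.7 FPKM (mean ± SD, n = 3), a log2 fold change of 5.33 ± 0.11 (SE, adjusted p = 1.73e-12). *MYMK*, which encodes the fusion protein myomaker, rose by 4.57 ± 0.10 on the log2 scale to 106 ± 5.56 FPKM, *FABP3*, a muscle fatty acid binding protein gene, by 4.74 ± 0.07 and *CKB*, a creatine kinase gene, by 4.38 ± 0.07. *MYOD1* rose from 24.7 ± 3.06 to 60.9 ± 10.4 FPKM and *MEF2C* by 2.37 ± 0.08 on the log2 scale, while *MYF5*, a myoblast determination factor, fell from 218 ± 10.3 to 66.6 ± 2.40 FPKM. Of 41 tested sarcomere genes 36 rose and 1 fell (median log2 fold change 2.60, adjusted p = 2.56e-21; adjusted p = 0.053 with an estimated correlation), among them *ACTN2* at 4.15, *MYH3* at 4.15 and *ACTA1* at 4.03. Excitation-contraction coupling genes rose in 20 of 22 cases (median 1.72, adjusted p = 6.84e-12), led by the fetal acetylcholine receptor subunit gene *CHRNG* at 4.11 and by *STAC3* at 4.04. Fusion and adhesion genes rose in 14 of 18 cases and fell in 3 (adjusted p = 1.28e-05), including *MYMX* at 4.19 and *JAM2* at 3.47. The differentiated-myocyte markers rose in all 18 cases (median 2.87), and 11 of 17 myogenic regulators rose while 3 fell (adjusted p = 0.0051; adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone, these counts were the same.

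Cell cycle genes fell over the same 24 h. All 45 tested S-phase genes fell (median log2 fold change -1.57, adjusted p = 2.56e-21), with the ribonucleotide reductase gene *RRM2* at -2.96 and the replication factor gene *CDC45* at -2.44. Of 59 G2/M genes 57 fell and 1 rose (median -2.34, adjusted p = 3.34e-28; 57 fell and 2 rose adjusted over the list alone), with the mitotic activator gene *CDC20* at -3.06, the mitotic kinase gene *CDK1* going from 49.1 ± 3.14 to 6.15 ± 0.630 FPKM and *CCNB2* from 38.3 ± 2.58 to 6.28 ± 0.828. Both lists kept their calls with an estimated correlation, at adjusted p = 0.0046 and 0.0072. *CDKN1C*, which encodes the cyclin-dependent kinase inhibitor p57, went from 0.968 ± 0.325 to 81.1 ± 13.5 FPKM (log2 fold change 5.38 ± 0.15, adjusted p = 2.70e-11), a value that rests on a low starting level and was 3.84 with a pseudocount of 5. *GADD45G* rose by 4.10 and *CDKN1A*, which encodes p21, by 2.02. Of the 18 cell cycle exit genes as a list, 9 rose and 5 fell (median 0.19, adjusted p = 0.040; adjusted p = 0.16 with an estimated correlation). That call ended without library T48_0 (median 0.19, adjusted p = 0.051), without the variance trend (0.062) and with only the 2 times compared (0.072).

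Cholesterol synthesis and uptake genes rose in 23 of 24 cases and none fell (median 1.71, adjusted p = 1.00e-16, and 0.019 with an estimated correlation), including *TM7SF2* at 3.15, *HMGCS1*, from 20.7 to 167 FPKM, and *INSIG1* at 2.49. Of 11 Notch pathway genes 9 rose and 1 fell (median 1.62, adjusted p = 1.28e-05; adjusted p = 0.081 with an estimated correlation; 10 rose adjusted over the list alone), with the ligand genes *DLL1* at 3.17 and *JAG2* at 2.10 and the target genes *HES1* at 2.37 and *HEY1* at 2.14. The unfolded protein and amino acid response list fell in 17 of 20 cases and rose in 1 (median -0.55, adjusted p = 4.42e-07; 19 fell adjusted over the list alone), with the asparagine synthetase gene *ASNS* at -1.68 and *PSAT1* at -1.46. Of 32 inhibitor-of-DNA-binding and serum response genes 19 fell and 6 rose (adjusted p = 0.0012; adjusted p = 0.16 with an estimated correlation; 20 fell adjusted over the list alone). *ID1*, whose product blocks myogenic factors, fell from 134 ± 2.45 to 8.16 ± 2.90 FPKM (log2 fold change -3.93 ± 0.17), *ID3* changed by -1.31 ± 0.08 and *HMGA2* by -2.17, whereas *FOS* rose by 2.13. The metallothionein genes, which encode metal-binding proteins, were among the largest falls: *MT2A* went from 4676 ± 126 to 298 ± 16.5 FPKM, with log2 fold changes of -4.67 ± 0.33 for *MT1G* and -3.49 ± 0.15 for *MT1M*. *ESM1* changed by -3.65 ± 0.12 and *NPTX2* by -3.55 ± 0.08, and *APOC1* rose by 4.42 ± 0.24. Interferon response genes rose in 11 of 20 cases and none fell (median 0.60, adjusted p = 0.0064; adjusted p = 0.44 with an estimated correlation), with *PSMB9* at 1.33 and *IFITM1* at 1.15. Respiratory chain genes fell in 27 and rose in 1 of 48 cases (median -0.17, adjusted p = 6.29e-04; adjusted p = 0.17 with an estimated correlation), a call that ended under quantile normalization (-0.06, adjusted p = 0.10). TGF-beta and BMP genes fell in 14 of 20 cases and rose in 4, with *TGFB3* at 2.57. That list had adjusted p = 0.033, and 0.11 with an estimated correlation, and lost its call under quantile normalization (-0.35, adjusted p = 0.087).

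Several lists did not pass as lists at 24 h against 0 h although members moved. Extracellular matrix genes rose in 17 and fell in 13 of 37 cases (adjusted p = 0.64), with *LUM* at 2.19, *LAMA4* at 1.75 and *TNC* at -1.59. Muscle energy genes rose in 7 and fell in 12 of 21 cases (adjusted p = 0.33), with a median of -0.23, a mean of 0.32 and a downward camera direction. *CKM* was at 3.15, and the muscle enolase gene *ENO3* went from 9.94 ± 1.17 to 79.8 ± 2.37 FPKM. The insulin-like growth factor axis rose in 5 and fell in 4 of 12 cases (adjusted p = 0.60), with *IGFBP5* at 2.60 and *IRS2* at -2.14. Ribosomal protein genes rose in 6 and fell in 11 of 44 cases (median -0.02, adjusted p = 0.39), a median that turned to 0.07 with adjusted p = 0.0080 under quantile normalization. Of the 8 transcription factors the study singled out on these same samples, 3 rose and 1 fell (2 and 1 adjusted over the list alone), with *ARID5B* at 0.73, *CUX1* at 0.51 and *XBP1* at -0.51 (adjusted p = 0.39 as a list). That list was chosen on these samples and is not independent evidence of its direction.

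Markers of other cell types were measured alongside. *PDGFRA*, a receptor gene of interstitial mesenchymal cells, rose from 1.92 ± 0.0348 to 7.03 ± 0.447 FPKM at 24 h (log2 fold change 1.46 ± 0.11). The interstitial mesenchymal list rose in 7 and fell in 3 of 13 cases (median 0.24, adjusted p = 0.11), with *LUM* at 2.19 and *PDGFRB* at 1.93, and passed with a filter at FPKM 5 (0.51, adjusted p = 0.027). *SPHK1* had a log2 fold change of -0.16 ± 0.10 (adjusted p = 0.21). Smooth muscle and pericyte genes rose in 4 and fell in 1 of 10 cases (adjusted p = 0.15), with *ACTA2* going from 34.7 to 455 FPKM and *LMOD1* at 1.27. Schwann and neural genes rose in 2 and fell in 2 of 5 cases (adjusted p = 0.75). Of the endothelial, immune and adipocyte markers only 3, 2 and 3 were expressed enough to test. *CD68* fell from 24.0 to 11 FPKM at 24 h, and *CD36* rose from 0.222 to 1.72. The myoblast list rose in 7 of 9 cases and fell in 2, with *NCAM1* at 2.39 (adjusted p = 8.11e-04; adjusted p = 0.13 with an estimated correlation).

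**Figure D1:**
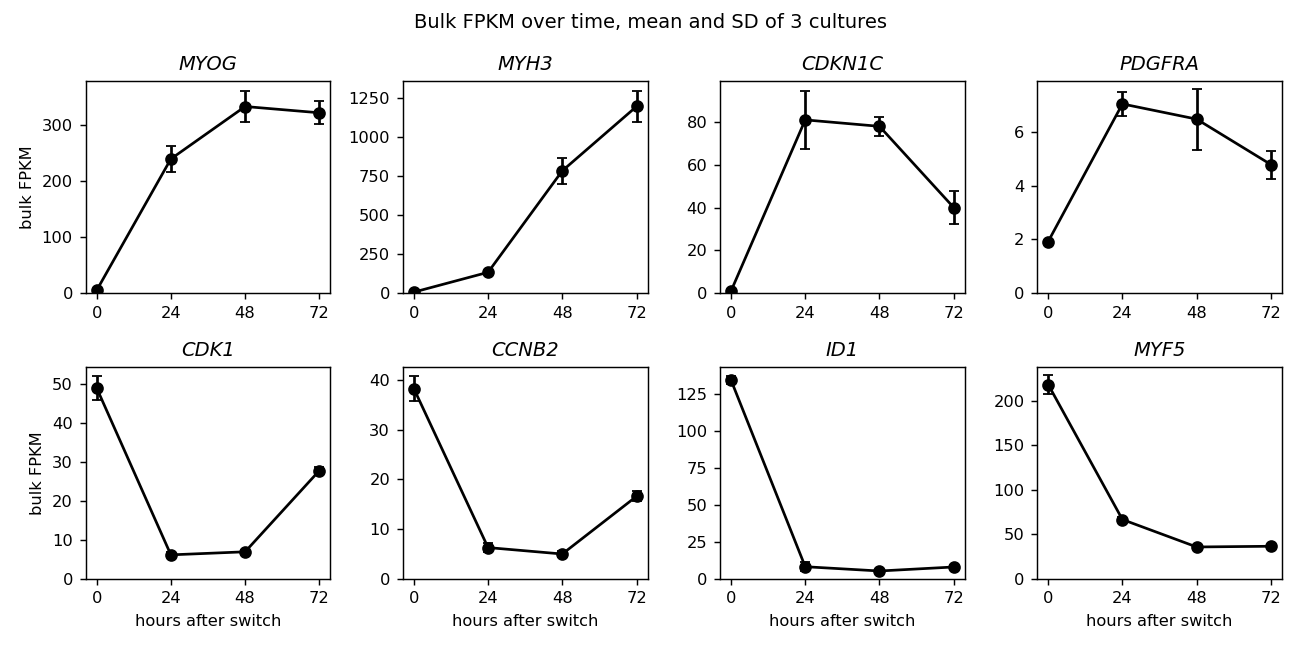
Bulk FPKM (vertical axis, from 0) of 8 genes against hours after the medium switch; points are means of 3 cultures and bars their SD. MYOG, MYH3, CDKN1C and PDGFRA were higher at 24 h than at 0 h, and CDK1, CCNB2, ID1 and MYF5 were lower. CDK1 and CCNB2 were higher at 72 h, in libraries of higher estimated depth, than at 48 h.

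At 48 h against 0 h, 7875 genes had changed (3842 higher, 4033 lower), 1688 of them at least 2-fold (817 with a pseudocount of 5). *MYOG* stood at 333 ± 27.6 FPKM, *ENO3* at 168 ± 16.4 and *CDKN1C* at 78.1 ± 4.54, while *MYF5* was at 35.7 ± 1.39, *CDK1* at 6.94 ± 0.384, *CCNB2* at 4.99 ± 0.569, *ID1* at 5.27 ± 0.446 and *ID3* at 41.8 ± 3.48. *MEF2C* was higher by 2.65 ± 0.08 and *PDGFRA* by 1.34 ± 0.11. *MYOD1* was higher by 0.38 ± 0.12 (adjusted p = 0.015), a call that ended without library T0_1 (0.30, adjusted p = 0.067). *SPHK1* had a log2 fold change of -0.02 ± 0.10 (adjusted p = 0.89).

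The whole course, 72 h against 0 h, asks how far the cells had gone. It changed 7672 genes (3760 higher, 3912 lower), 129 of them at least 8-fold, with a higher estimated depth of the 72 h libraries as given above. The 10 largest rises by the naming rule were contractile or calcium-handling genes. *MYH3*, the embryonic myosin heavy chain gene, went from 6.62 ± 0.495 to 1197 ± 98.7 FPKM (log2 fold change 7.30 ± 0.08, adjusted p = 1.24e-14), and *MYL11*, a fast skeletal myosin light chain gene, from 18 ± 1.5 to 2115 ± 94.1. *TNNC2* rose by 6.76 ± 0.11, *ACTN2* by 6.17 ± 0.11, *ACTA1* by 5.96 ± 0.10, *MYH8* by 5.95 ± 0.09, *CASQ2* by 5.94 ± 0.10, *MYL4* by 5.84 ± 0.09, *TNNT3* by 5.81 ± 0.10 and *MYL1* by 5.78 ± 0.10. Of the sarcomere list 40 of 41 rose and 1 fell (median 3.84, adjusted p = 6.84e-30, and 0.029 with an estimated correlation). The largest falls by the naming rule were *MT1G* at -5.81 ± 0.33, *NPTX2* at -4.67 ± 0.08, *MT1M* at -4.16 ± 0.15, *ID1* at -3.92 ± 0.17, *MT2A* at -3.61 ± 0.07 and *MT1E* at -3.43 ± 0.08. They also held the chemokine genes *PPBP* at -4.36 ± 0.19 and *CXCL5* at -3.71 ± 0.12, *ITGA10* at -3.34 ± 0.13 and the glucocorticoid-responsive gene *FKBP5* at -3.29 ± 0.05.

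At 72 h the cell cycle lists were still below their 0 h level, with 43 of 45 S-phase genes (median -0.99) and 57 of 59 G2/M genes (median -0.92) lower. *CDK1* changed by -0.80 ± 0.07 and *CCNB2* by -1.16 ± 0.10. *MYOG* was at 322 ± 20.9 FPKM, *MEF2C* at 107 ± 14.4, *ENO3* at 232 ± 17 and *CDKN1C* at 40.1 ± 7.74. *MYF5* was at 36.5 ± 1.22, *ID3* at 48.3 ± 2.36 and *PDGFRA* at 4.78 ± 0.520, higher than at 0 h by 0.98 ± 0.11. *MYOD1* changed by -0.48 ± 0.12 (adjusted p = 0.0042). *SPHK1* had 0.21 ± 0.10 (adjusted p = 0.10), and passed with only the 2 times compared (0.039) and without T24_2 (0.021). Respiratory chain genes were higher in 23 and lower in 6 of 48 cases (median 0.16, adjusted p = 0.013; adjusted p = 0.34 with an estimated correlation), with the muscle isoforms *COX6A2* at 4.48 and *COX7A1* at 2.04. *CD36*, a fatty acid transporter gene also on the adipocyte list, went from 0.222 to 20.4 FPKM.

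On the second day, 48 h against 24 h, the contractile rise went on and the amino acid response list rose. Sarcomere genes rose in 35 of 41 cases and fell in 1 (mean 1.22, adjusted p = 5.65e-31; adjusted p = 0.059 with an estimated correlation), with *MYH8* up by 2.80 ± 0.09 and *MYH3* by 2.54 ± 0.08. *CASQ2* rose by 2.41 ± 0.10 and *BCAS1* by 2.49 ± 0.12. The unfolded protein and amino acid response list rose in 19 of 20 cases and none fell (median 1.10, adjusted p = 3.67e-29, and 0.0014 with an estimated correlation; 20 rose adjusted over the list alone). *CHAC1*, a glutathione-degrading enzyme gene, rose by 2.33 ± 0.14, *PSAT1* by 2.25, *ASNS* from 19.3 to 94.5 FPKM and *TRIB3* by 2.17. Cholesterol genes fell in 13 of 24 cases and rose in 1 (median -0.26, adjusted p = 1.25e-05; adjusted p = 0.20 with an estimated correlation). In the cell cycle lists 52 of 59 G2/M and 36 of 45 S-phase genes did not pass. Median, mean and camera direction differed in sign for the S-phase, respiratory chain, fusion, insulin-like growth factor, TGF-beta, serum response and study regulator lists, none of which passed. Falls included the immediate early genes *EGR1* at -1.86 ± 0.10 and *FOS* at -1.73 ± 0.23, *CPA4* at -1.88 ± 0.11, *DPP4* at -1.75 ± 0.11, *LINC03033* at -1.51 ± 0.07 and *CAVIN2* at -1.44 ± 0.05. *LANCL1-AS1* rose by 2.53 ± 0.24, a value that cannot be separated from its sense partner without strand.

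Among the fixed genes on the second day, *MYOG* rose by 0.48 ± 0.11 and *ENO3* by 1.06 ± 0.09, and *MYOD1* changed by -0.88 ± 0.12, *MYF5* by -0.88 ± 0.05 and *ID3* by -0.59 ± 0.08. *CDK1* (0.15 ± 0.07, adjusted p = 0.17), *CCNB2* (-0.28 ± 0.10, 0.053), *ID1* (-0.50 ± 0.17, 0.056), *PDGFRA* (-0.11 ± 0.11, 0.52), *SPHK1* (0.14 ± 0.10, 0.38) and *CDKN1C* (-0.04 ± 0.15, 0.88) did not pass, with log2 fold change, SE and adjusted p in that order. *CCNB2* passed without library T24_0 (-0.34, adjusted p = 0.043) or T48_1 (-0.34, 0.047), and *ID1* without T24_1 (-0.73, adjusted p = 0.0026). Both also passed with a filter at FPKM 5 (0.043 each) and under quantile normalization (0.045 and 0.046), and *CCNB2* with a pseudocount of 0.1 (0.047) and with centred libraries (0.046). *MEF2C* rose by 0.28 ± 0.08 (adjusted p = 0.033), and that call ended without T24_1 (0.28, 0.076), T24_2 (0.25, 0.10), T48_1 (0.28, 0.076) or T48_2 (0.23, 0.11), with no filter (0.083) and with no variance trend (0.061).

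On the third day, 72 h against 48 h, mitotic genes rose. Of 59 G2/M genes 53 rose and 1 fell (median 1.32, adjusted p = 1.92e-36, and 0.0061 with an estimated correlation; 54 rose adjusted over the list alone), and 39 of 45 S-phase genes rose and none fell (median 0.47, adjusted p = 1.49e-14, and 0.0089 with an estimated correlation; 40 rose adjusted over the list alone), with *RAD51AP1* at 1.28 and *RRM2* at 1.23. *UBE2C* went from 8.05 ± 0.716 to 38.1 ± 1.59 FPKM, *CDK1* from 6.94 ± 0.384 to 27.8 ± 0.885 (log2 fold change 1.86 ± 0.07, adjusted p = 5.70e-08), *CCNB1* from 7.96 ± 0.306 to 31.5 ± 2.61, *NUSAP1* rose by 1.97 ± 0.11, *NUF2* by 1.78 ± 0.09 and *CCNB2* by 1.56 ± 0.10. *GSG1* rose by 2.05 ± 0.15. The 72 h libraries of this comparison had a higher estimated depth than those of 48 h. Respiratory chain genes rose in 37 of 48 cases and none fell (median 0.34, adjusted p = 8.72e-17, and 0.021 with an estimated correlation; 39 rose adjusted over the list alone), with *COX7A1* at 1.35. Ribosomal protein genes rose in 39 of 44 cases, and in 43 adjusted over the list alone (median 0.27, adjusted p = 4.64e-22; adjusted p = 0.13 with an estimated correlation), a call that ended under quantile normalization (median 0.02, adjusted p = 0.053). Sarcomere genes rose in 23 cases and fell in 4 (adjusted p = 7.76e-07; adjusted p = 0.30 with an estimated correlation), with *LMOD2* at 1.70, *MYL3* at 1.67, the slow myosin gene *MYH7* at 1.29 and *MYBPC2* at -1.55. Adjusted over the list alone, 25 rose and 4 fell.

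*MYMX*, whose product acts with myomaker in fusion, went from 33 ± 2.2 to 7.46 ± 0.524 FPKM on the third day (log2 fold change -2.01 ± 0.09), while 5 of 18 fusion and adhesion genes rose and 6 fell (adjusted p = 0.61; 6 and 7 adjusted over the list alone). Notch genes fell in 9 of 11 cases and none rose (median -0.45, adjusted p = 1.08e-05; adjusted p = 0.11 with an estimated correlation; 10 fell adjusted over the list alone), with *NOTCH3* at -1.09 and *HEY1* at -0.98. Extracellular matrix genes fell in 25 and rose in 7 of 37 cases (median -0.34, adjusted p = 7.31e-08; adjusted p = 0.11 with an estimated correlation; 26 fell adjusted over the list alone), with *FBLN5* at -1.03, *VCAN* at -0.99 and *LUM* at -0.89. *ADGRG1* changed by -1.61 ± 0.10, *SELENOP* by -1.53 ± 0.14, *PAMR1* by -1.44 ± 0.07, *TGM2* by -1.37 ± 0.08 and *APOC1* by -1.36 ± 0.24. *CDKN1C* changed by -0.96 ± 0.15 and *MYOD1* by -0.87 ± 0.12, and *ENO3* rose by 0.46 ± 0.09. *MYOG* (-0.05 ± 0.11, adjusted p = 0.78), *MYF5* (0.03 ± 0.05, 0.67), *MEF2C* (-0.21 ± 0.08, 0.075), *ID3* (0.20 ± 0.08, 0.064) and *SPHK1* (0.23 ± 0.10, 0.11) did not pass. *MEF2C* passed without T72_0 (-0.30, adjusted p = 0.020) and under quantile normalization (-0.31, 0.014), and *MYF5* turned to -0.01 (0.90) under the latter. Without T48_2 *MYOG* turned to 0.0092 (adjusted p = 0.97). *ID3* passed without T24_0 (0.20, 0.038) or T48_0 (0.26, 0.043), with a filter at FPKM 5 (0.049) or with centred libraries (0.048), and *SPHK1* without T24_2 (0.23, 0.024) or with only the 2 times (0.026). *PDGFRA* changed by -0.36 ± 0.11 (adjusted p = 0.026), a call that ended without T48_0 (-0.25, 0.11), T48_1 (-0.36, 0.059), T72_0 (-0.36, 0.066) or T72_1 (-0.30, 0.10), with no filter (0.057) or with only the 2 times (0.066). *ID1* rose by 0.51 ± 0.17 (adjusted p = 0.040), which ended without T0_0, T0_1, T0_2 or T24_2 (0.51, with 0.051, 0.051, 0.051 and 0.050), T48_0 (0.46, 0.12), T48_1 (0.52, 0.075), T48_2 (0.56, 0.058), T72_1 (0.47, 0.12) or T72_2 (0.46, 0.11), with a pseudocount of 5 (0.33, 0.050), no filter (0.11) or no variance trend (0.058).

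**Figure D2:**
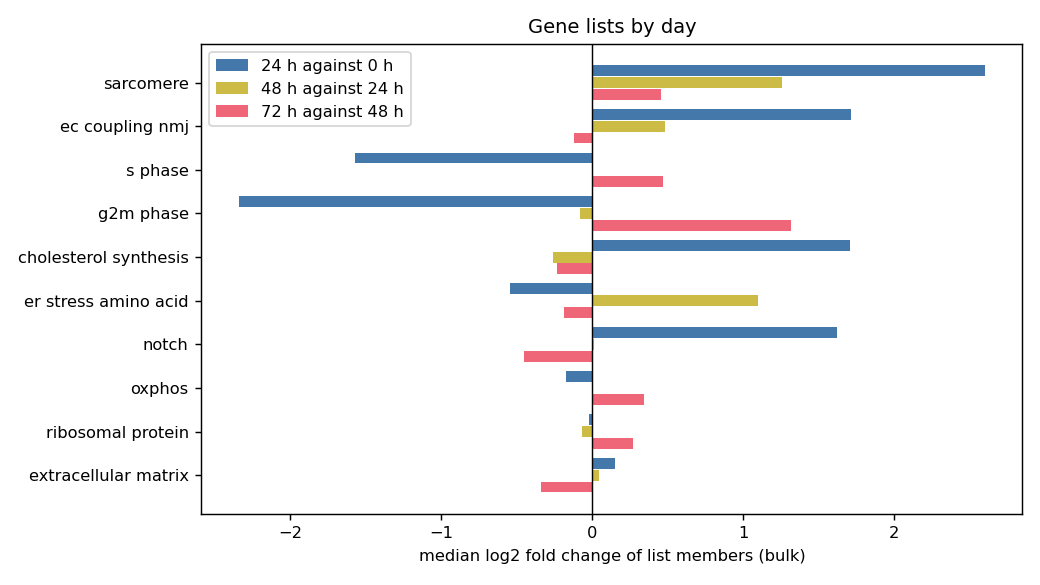
Median log2 fold change in bulk of the tested members of 10 gene lists (horizontal axis, bars from 0) on each of the 3 days. Sarcomere genes were highest on the first day, the unfolded protein and amino acid response list turned from -0.55 to 1.10, and G2/M genes from -2.34 on the first day to 1.32 on the third; the ribosomal protein median of the first day turns sign under quantile normalization.

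In single cells the same genes were followed as the share of cells with a transcript, with 1 pooled sample and 1 plate per time and no test. *MYOG* was present in 2 of 75 cells at 0 h (2.67%, exact 95% interval 0.325 to 9.30), 26.3% at 24 h (16.9 to 37.7), 22.4% at 48 h (14 to 32.7) and 37.3% at 72 h (25 to 50.9). *MYH3* was present in 6.67, 22.4, 47.1 and 91.5% of cells, *ENO3* in 14.7, 31.6, 47.1 and 50.8%, and *CDKN1C* in 6.67, 67.1, 54.1 and 62.7%. The mean FPKM of *MYH3* over cells went from 1361 (SD 9468) at 48 h to 216 (SD 595) at 72 h, while its share rose. Its mean log2(FPKM + 1) over cells rose from 3.21 to 4.61 between these times. The fall was therefore one of the arithmetic mean, whose SD at 48 h was far above it. *CDK1* went from 52% (40.2 to 63.7) at 0 h to 7.89% at 24 h (2.95 to 16.4), 9.41% at 48 h and 18.6% at 72 h (9.69 to 30.9). *CCNB2* was in 68, 21.1, 20 and 27.1%, *MYF5* in 68, 32.9, 37.6 and 25.4%, *ID1* in 68, 21.1, 21.2 and 47.5%, and *ID3* in 96, 65.8, 64.7 and 83.1%. *PDGFRA* went from 5.33% (1.47 to 13.1) to 27.6% (18 to 39.1), 20% and 35.6% (23.6 to 49.1). *DES*, a muscle intermediate filament gene, was in 72, 63.2, 60 and 61% of cells, *MEF2C* in 61.3, 59.2, 63.5 and 84.7%, *MYOD1* in 21.3, 23.7, 8.24 and 15.3%, and *SPHK1* in 20, 9.21, 15.3 and 30.5%. Median genes per cell were 6021, 5438, 5562 and 6549, so part of a difference between plates is a difference in detection.

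Of the transcription factors singled out by the study, *ARID5B* was in 90.7, 96.1, 90.6 and 96.6% of cells, *CUX1* in 69.3, 77.6, 82.4 and 81.4%, *XBP1* in 64, 47.4, 71.8 and 76.3% and *AHR* in 64, 47.4, 55.3 and 81.4%. *POU2F1* was in 22.7 to 26.3%, *USF1* in 10.5 to 20.3%, *MZF1* in 10.5 to 30.5% and *ZIC1* in 8.24 to 13.2%. The largest increases in share from 0 to 72 h were in *MYL12-AS1* (1.33 to 98.3%), *A2ML1-AS2* (8.0 to 94.9%), *MYH3*, *OLFML2A* (8.0 to 84.7%), Metazoa_SRP (13.3 to 88.1%) and *MYL11* (8.0 to 81.4%). Metazoa_SRP is here 1 identifier named after the signal recognition particle RNA. *MYL12-AS1*, *A2ML1-AS2* and Metazoa_SRP were present in at most 22.4% of cells at 48 h or earlier, and in 54.5, 54.5 and 63.6% of the 72 h wells scored as empty. The antisense genes among them cannot be separated from their sense partners without strand. *MYH3*, *OLFML2A* and *MYL11* were not looked up in the empty wells. The largest decreases were in *LINC03033* (81.3 to 11.9%), *DKK1* (90.7 to 23.7%), *MT1G* (72 to 5.08%), *METTL7B* (72 to 13.6%), *TK1* (76 to 18.6%) and *CDC45* (65.3 to 10.2%).

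**Figure D3:**
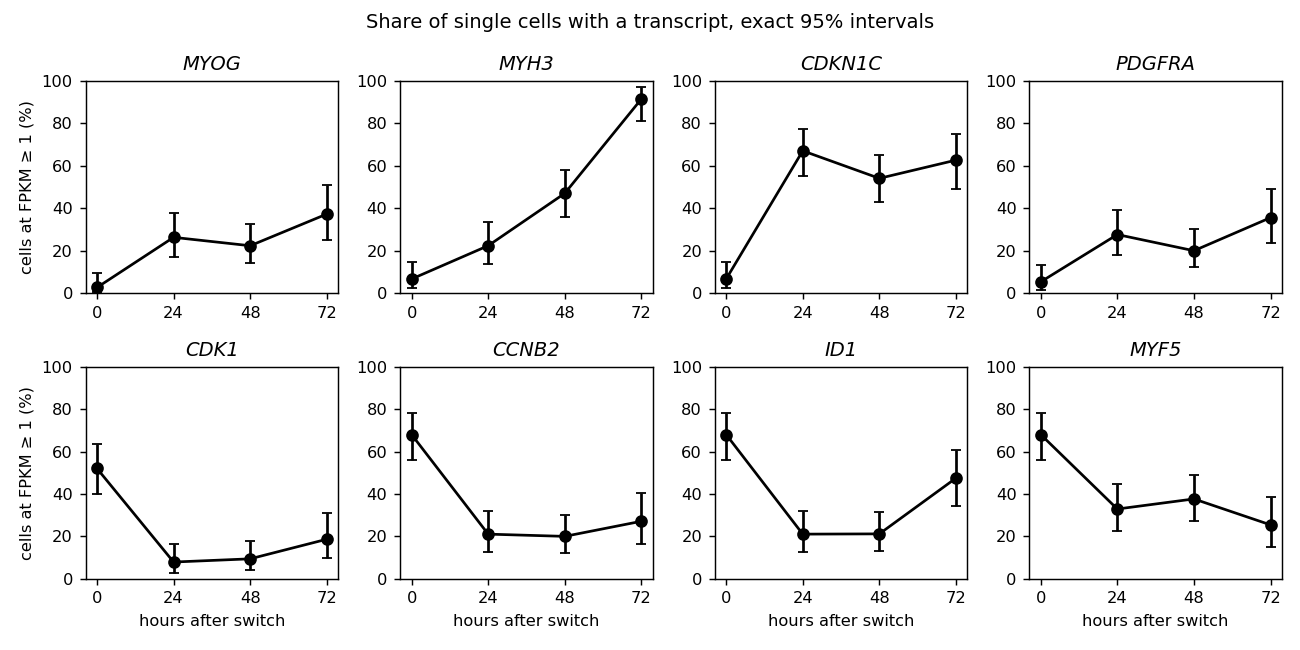
Share of single cells (vertical axis, percent) with 8 genes at FPKM 1 or more against hours after the medium switch; bars are exact 95% intervals for counting error only, with 75, 76, 85 and 59 cells. MYOG went from 2.67 to 37.3% and CDK1 from 52 to 18.6%.

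Pairs of genes were compared within each time, so that plate and time do not enter. Cells of a time still differed in genes detected (2331 to 9482 at 72 h), for which pairs were not adjusted. Overlap of intervals is given as a description and does not rule out a difference. After the switch *PDGFRA* was present in fewer cells with *MYOG* than without it: 1 of 20 (5.0%, 0.127 to 24.9) against 35.7% (23.4 to 49.6) at 24 h, 5.26% (0.133 to 26) against 24.2% (14.5 to 36.4) at 48 h, and 22.7% (7.82 to 45.4) against 43.2% (27.1 to 60.5) at 72 h, with overlapping intervals at each time. At FPKM 0.1 as the threshold the 24 h shares were 26.9% (11.6 to 47.8) with *MYOG* and 44% without. *PDGFRA* was also in fewer cells with *DES* than without it, 12.5% (4.73 to 25.3) against 53.6% (33.9 to 72.5) at 24 h, 11.8 against 32.4% at 48 h and 22.2 against 56.5% at 72 h, with overlapping intervals at the latter times. At FPKM 0.1 the intervals overlapped at 24 h too (28.6 against 65%). At 72 h *SPHK1* was in 57.1% (34 to 78.2) of cells with *PDGFRA* and 15.8% (6.02 to 31.3) of those without, and at 24 and 48 h in 19 and 29.4% against 5.45 and 11.8%, with overlapping intervals. At FPKM 5 the intervals overlapped at 72 h too (33.3 against 11.4%), and the 48 h shares were 9.09 and 8.11%. *CDK1* in cells with and without *MYOG* was 10 and 7.14% at 24 h, 10.5 and 9.09% at 48 h, and 13.6 and 21.6% at 72 h, differences within the intervals. *CCNB2* was in 63.6 to 89.7% of cells with *CDK1* and 14.3 to 44.4% of those without, with overlapping intervals at 24 and 72 h, and at 0 h too at FPKM 0.1 (90.9 against 67.7%). At 24, 48 and 72 h in that order, *MEF2C* was in 100, 94.7 and 90.9% of cells with *MYOG* against 44.6, 54.5 and 81.1% of those without, with overlapping intervals at 72 h. At FPKM 0.1 the *MEF2C* intervals overlapped at each time (96.2 against 68%, 83.3 against 67.3% and 93.9 against 96.2%). *ENO3* was in 60, 94.7 and 72.7% against 21.4, 33.3 and 37.8%, also overlapping at 72 h. *CDKN1C* was in 90, 78.9 and 86.4% against 58.9, 47 and 48.6%, and *ID1* in 5.0, 5.26 and 40.9% against 26.8, 25.8 and 51.4%, with overlapping intervals at each time. *MYF5* was in 20, 31.6 and 31.8% against 37.5, 39.4 and 21.6%, so its direction differed between times, within overlapping intervals, and at FPKM 0.1 the 24 h shares were 42.3 and 40%.

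Across the 14006 genes tested in bulk, the mean of cells and the bulk mean had a Spearman rho of 0.80, 0.74, 0.75 and 0.77 at the 4 times (Pearson r on the log2 scale 0.83, 0.78, 0.79 and 0.81). Changes against 0 h had a rho of 0.46 at 24 h, 0.49 at 48 h and 0.42 at 72 h, and the mean of cells went the same way for 68.8, 68.6 and 69.2% of the genes called in bulk. From 48 to 72 h rho was 0.18 and the share 60.2%, and from 24 to 48 h 0.19 and 68%. The 6 tube controls, of 0, 24 and 48 h, had a rho of 0.57 to 0.71 with bulk and 0.65 to 0.89 with the mean of cells. These relations are across genes, which are not independent replicates.

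Within each time, cells were ordered by the sarcomere score. Spearman rho is given for 24, 48 and 72 h in that order. The screen held 10340 genes, from which those of the sarcomere list were then left out of the ranking, as was the 0 h time. Those higher in cells of high score by the smallest rho over these 3 times were *ANKRD1* (0.82, 0.81, 0.80), *IL32* (0.76, 0.78, 0.83), *DES* (0.79, 0.76, 0.80), the intermediate filament gene *NES* (0.76, 0.79, 0.81), *MEF2C* (0.83, 0.75, 0.76), the adhesion gene *NCAM1* (0.86, 0.74, 0.75), *KLHL30* (0.78, 0.71, 0.74) and *SELENOW* (0.72, 0.72, 0.71). Those lower by the same rule were *NRP1* (-0.66, -0.64, -0.66), *IGFBP4* (-0.63, -0.81, -0.63), *MLPH* (-0.65, -0.61, -0.63), *FTL* (-0.75, -0.66, -0.60), *FAP* (-0.62, -0.60, -0.67), *SOX4* (-0.60, -0.74, -0.65), *MGST1* (-0.60, -0.61, -0.68) and *TAGLN2* (-0.66, -0.58, -0.62). At 0 h the relation was weak or absent for some: rho was 0.19 for *SELENOW*, -0.10 for *FTL*, 0.02 for *FAP* and -0.16 for *SOX4*. The other genes named by this rule kept their direction at 0 h, at 0.67 to 0.79 for those higher and -0.27 to -0.72 for those lower. Of genes on the fixed lists, those named here being picked after their values were seen, *MYOG* had 0.62, 0.55 and 0.61, *MYMK* 0.73, 0.65 and 0.54, *CAV3* 0.76, 0.69 and 0.69, and *CDKN1C* 0.42, 0.51 and 0.59. *HMGA1* had -0.68, -0.55 and -0.65, *HMGA2* -0.65, -0.45 and -0.60, *EGR1* -0.53, -0.45 and -0.48, and *PDGFRA* -0.48, -0.23 and -0.52. *ARID5B* had -0.29, -0.52 and -0.14, and was positive at 0 h (0.25). Cells of a time share a plate and a pool, so these values describe the cells and carry no test.

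Clustering of all cells into 6 groups gave 2 myocyte-like clusters, led by *MYH3*, *TNNT2* and *TTN* (15 cells, median 2520 genes) and by *TNNI1*, *ACTC1* and *TNNT2* (58 cells), and a proliferating-like cluster led by *NUSAP1*, *CDKN3* and *PRC1* (21 cells). The other clusters are left by number: cluster 2 (61 cells) led by *IGDCC4*, *H19* and *CHRNA1*, cluster 4 (92 cells) by *DHRS3*, *MGST1* and *IGFBP4*, and cluster 6 (48 cells, 47 of them from 0 h) by *MYF5*, *LINC03033* and *NPTX2*. Cluster 4 had the interstitial mesenchymal markers as its best list, by a mean log2 difference of 0.63, with none of them among its 10 leading genes. For cluster 2 the best list was the myoblast markers, at 1.29, with 1 of them among its 10 leading genes. For cluster 6 it was the proliferating markers, at 1.71 against 3.93 in the proliferating-like cluster, with none among its 10 leading genes. Proliferating markers were thus not confined to the cluster of 21 cells. With 1 plate per time, a cluster mostly of 1 plate may be that plate. Cluster sizes were not compared between times. With 4 or 8 clusters in place of 6, the cluster led by *MYH3* and that led by *DHRS3* held the same numbers of cells, 15 and 92. These were cuts of the same tree, so an unchanged cluster is no sign of stability. With 4, the *TNNI1* cluster joined cluster 2 (119 cells) and the proliferating-like cluster joined cluster 6 (69 cells). With 8, the *TNNI1* cluster was split into 23 and 35 cells, the latter with myoblast markers as its best list.

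Wells that the imaging scored as holding a cell and those scored as empty overlapped in content. The median number of genes at FPKM 1 or more was 5878, 5438, 5562 and 6516 in wells with 1 cell, and 3307, 1968, 2002 and 2811 in empty wells (8, 15, 8 and 11 wells). Wells with 2 cells had 6506 genes at 0 h (4 wells) and 6514 at 24 h (2 wells), and the single such well at 72 h had 7412. The 8 wells with debris at 72 h had a median of 6453 genes. The debris class took in wells scored with and without a cell. At least some of those at 72 h were scored as holding a cell, so their median does not describe debris alone. Tube controls had medians of 7365, 6166 and 6870. Mitochondrial transcripts held a median of 6.95 to 9.11% of FPKM in wells with 1 cell and 1.44 to 2.52% in empty wells.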

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

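Wells scored as holding no cell were used only to describe the wells and to check 3 RNAs of the 72 h plate, and they still gave signal. Of 42 such wells, 38 had at least 1000 genes at FPKM 1 or more and 15 had at least 3000, as most wells with 1 cell did. At 72 h, 5 of the 11 empty wells reached 3000 genes, and the highest held 9649. No biological explanation was tested for these wells. Among the small groups of wells, the 4 wells with 2 cells at 0 h came closest to holding an outlier in genes per well, with a gap of 0.798 of the range against a critical value of 0.829, so none passed.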

How the results depend on the processing

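The fit without the 72 h libraries, the replicate block and the rescaling of cells were chosen after seeing the data; all other alternatives were planned. Counts of changed genes stayed within 1.5 times their value under every alternative run, at 7954 to 10025 over the 4 times, 6225 to 7703 at 24 h, 6306 to 8107 at 48 h and 6243 to 7859 at 72 h against 0 h, 2495 to 3323 for 48 h against 24 h and 3438 to 4427 for 72 h against 48 h. Leaving out 1 library gave 9241 to 9621, 6955 to 7703, 7182 to 7867, 6870 to 7687, 2495 to 3158 and 3438 to 4355 in the same order. Without the 72 h libraries the counts were 8318 over the 3 remaining times, 7316, 7511 and 2785. Counts of 2-fold changes moved by more than 1.5 times in 7 of 105 cases, all under another pseudocount: with 0.1, 407 for 48 h against 24 h and 398 for 72 h against 48 h, and with 5, 654, 817 and 637 at 24, 48 and 72 h against 0 h, 90 for 48 h against 24 h and 62 for 72 h against 48 h. Of 2331 recomputed values of named genes 27 lost and 20 gained their call, and of 2510 list values 25 lost and 31 gained it, not counting values that changed direction. The suffix of the bulk columns, which was not matched to the replicate numbers of the labels, was fitted as a replicate block. The counts were then 9627 over the 4 times, 7534, 7724 and 7537 at 24, 48 and 72 h against 0 h, 2930 for 48 h against 24 h and 4122 for 72 h against 48 h. The calls of *MEF2C* at 48 h against 24 h, *ID1* at 72 h against 48 h and the cell cycle exit list at 24 h against 0 h ended (adjusted p = 0.052, 0.057 and 0.054), and *ID3* at 72 h against 48 h passed (0.023). Libraries sharing a suffix did not deviate together from the means of their times: the correlation was -0.13 to 0.035 over 18 pairs, and the best match at another time had the same suffix in 7 of 36 cases. The lack of correlation does not show that they share nothing but a number.

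Direction changed in 4 recomputed gene values and 24 list values, 26 of which passed in neither fit; for lists it is the direction of camera, beside which the median is given. Under quantile normalization the ribosomal protein median was 0.073 at 24 h and 0.030 at 48 h against 0 h, the insulin-like growth factor axis 0.0098 at 48 h against 0 h, the smooth muscle list 0.018 and *MYF5* -0.010 at 72 h against 48 h. The insulin-like growth factor axis at 48 h against 0 h was 0.0012 with no filter and -0.053 with a filter at FPKM 5, which gave 5.8e-04 for the respiratory chain at 48 h against 24 h. Also at 48 h against 24 h, the Schwann list was 0.031 with a pseudocount of 0.1 and 0.052 with no trend, and the interferon list -0.018 with only the 2 times. Leaving out 1 library gave -0.077 to 0.030 for *SPHK1* and -0.12 to 0.026 for the insulin-like growth factor axis at 48 h against 0 h; -0.17 to 0.072 for *CDKN1C*, -0.020 to 0.0059 for S-phase, -0.028 to 0.026 for respiratory chain, -0.17 to 0.086 for interferon and -0.058 to 0.15 for Schwann genes at 48 h against 24 h; and -0.11 to 0.0092 for *MYOG* and -0.061 to 0.35 for interferon genes at 72 h against 48 h. The cause was not tested.

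In cells, 100 of 992 recomputed shares left their interval, none of them under the rescaling to a common total, which gave *MYOG* in 39% at 72 h. Detection at FPKM 0.1 gave *MYOG* in 35.3% at 48 h and 55.9% at 72 h, *PDGFRA* in 31.8% at 48 h, and *PDGFRA* in 26.9% of cells with *MYOG* at 24 h (44% of those without). Detection at FPKM 5 gave *MYOG* in 23.7% at 72 h, and, among cells with *MYOG*, *CDK1* in 0% at 0 and 72 h and *PDGFRA* in 0% at 0 and 48 h. With the median of cells in place of the mean, rho with bulk was 0.75, 0.67, 0.68 and 0.71 for levels, 0.38, 0.38 and 0.25 for changes at 24, 48 and 72 h against 0 h and 0.086 for 72 h against 48 h. Given the number of genes detected, rho of *CDK1* with the sarcomere score at 0 h was -0.33. Of 824 recomputed rho values 59 moved and 23, in 17 genes, changed sign, none from further than 0.055 from 0. Median genes per well with 1 cell were 6470 and 6534 at 24 and 48 h at FPKM 0.1, and 4129 and 4222 at FPKM 5. The lower thresholds count more genes by construction. Single-cell depth differed between plates, which limits what shares show between times.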

Other observations

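The tests of G2/M genes against depth, of *SLC30A1*, and the counts over other splits were chosen after the results they bear on were seen; the others were written down before. For the RNAs of the 72 h plate, the rules that a gene near the floor or a share whose interval reaches below 25% decides nothing were added after their values were seen.

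Genes known to respond to glucocorticoids, a list not used in the comparisons, mostly fell after the medium switch. Of 12 tested targets whose values had not been seen, 9 fell from 0 to 24 h and 3 rose (median log2 fold change -0.64, lower than 99.99% of 10000 lists matched on mean FPKM). *ERRFI1* went from 152 to 53.1 FPKM, *SGK1*, a serum- and glucocorticoid-regulated kinase gene, from 41.3 to 16.6, *ANGPTL4* from 65.8 to 24.9, *KLF9* from 12.7 to 5.54 and *GLUL* from 148 to 87.3. *TSC22D3* fell less, from 55.7 to 44, and was at 53 at 72 h, which a lasting loss of the hormone would not predict. The other targets that fell stayed further below their 0 h level at 72 h, such as *SGK1* at 14.2 and *GLUL* at 66.1 FPKM. *CEBPD*, *CRISPLD2* and *PDK4* rose by 0.55, 0.82 and 1.14. *FKBP5*, which had prompted the list, changed by -1.94 at 24 h, and *MT1X* by -2.56.

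A candidate explanation for the fall of the metallothioneins and *FKBP5* is the loss of a glucocorticoid with the growth medium, and the 9 falls among 12 targets go with it. The labels do not list the hormones of either medium, and several of these targets also respond to serum, which changed at the same time, so hormone and serum stay confounded. A lower metal supply is a second hypothesis, for the metallothioneins only: *SLC30A1*, a zinc-responsive transporter gene, changed by -0.33 (adjusted p = 6.17e-04 in limma). That is weak evidence, since 3987 of 14006 genes fell in the same comparison. Neither explanation is excluded.

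The G2/M genes that rose from 48 to 72 h in bulk invite a second look, since the 72 h libraries had a higher estimated depth. Their median change of 1.32 exceeded the highest of 10000 lists matched on FPKM averaged over the 4 times (0.15, median -0.01). That argues against depth as the whole cause. Genes matched in this way can start higher at 48 h than the G2/M genes, which fell after 0 h. The lists are thus no close match for an effect of depth on low values. More cycling cells at 72 h is the biological hypothesis. In single cells 53 of 57 other G2/M genes were in a larger share of cells at 72 h than at 48 h. Their median change was 6.50 points, against 6.46 in lists matched on the share averaged over the 4 times. G2/M genes fell after 0 h, as *CDK1* did (52% of cells at 0 h, 9.41% at 48 h), so matched genes can start from a higher share at 48 h. A like gain in points therefore does not show that the G2/M rise equals that of other genes. Whether more cells cycled or each cycling cell held more mRNA cannot be told apart here, because detection rose across the whole 72 h plate.

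*MYL12-AS1*, *A2ML1-AS2* and Metazoa_SRP were in 88.1 to 98.3% of cells on the 72 h plate. A signal carried by the whole plate could explain it: at least 54.5% of its 11 empty wells held each RNA (exact 95% interval 23.4 to 83.3), against 0% of the 24 and 48 h empty wells and, for Metazoa_SRP only, 2 of 8 at 0 h. But 5 of those 11 wells had 3000 genes or more and may hold cell RNA, so a rise in the cells themselves stays open. In bulk the only tested RNA, Metazoa_SRP, changed by 0.49 ± 0.54 (SE) near the floor, being listed at 0 at 48 h, *A2ML1-AS2* was listed at 0 in every library and *MYL12-AS1* stayed below 1 FPKM. The explanations cannot be told apart, as empty wells are few and bulk values low.

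For the F test over the 4 times, 1 of 100 splits of the libraries, the real one, called as many genes (9845, against 7993 in the highest other). That share of 0.01 is the lowest that 100 splits can give, so it makes chance unlikely without excluding it. Mixed splits, here and below, also put differences between times into the spread, which lowers their calls. For 3 against 3 libraries only 10 splits exist, too few for a share under 0.05: 1 split called as many in each comparison, with 7646, 7875, 7672, 3196 and 4362 genes in the real splits and at most 1, 1, 0, 1 and 1 in the others.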
